A study of Mus musculus with 3 samples.

How the data were processed

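The series measured transcript levels in mouse retina with Affymetrix U74Av2 oligonucleotide arrays, named in the sample titles, which carry 1 signal per probe set, a group of short probes against a single transcript or a set of related transcripts. Per the labels, total RNA came from neural retinas of wild-type mice at postnatal day 10. The mice had a mixed 129/SvEv and C57BL/6 background, and Rp1 mutant littermates were studied in parallel. Each of the 3 samples was a pool of the retinas of 3 to 4 mice, collected between 1 and 2 pm. The titles of pools 2 and 3 carry the name Rp1 and that of pool 1 does not, whereas the descriptions of all 3 call the mice wild type, and the grouping follows the descriptions. Every sample falls into 1 group, so no comparison between groups was made, and the mutant samples were not analysed here. The pools are numbered 1 to 3 in accession order, and these numbers only name them. The labels do not say whether any mouse gave tissue to more than 1 pool, and no labelling or scanning batch is given in the sources used here.

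The deposited table holds 12488 probe sets on each array as a linear intensity that is never negative. How the authors condensed the probe readings into this intensity, and with which software, is not given in the sources used here. The mean after trimming 2% of the values at each end was 500.3 on array 1, 500.2 on array 2 and 500.3 on array 3, which is what global scaling of the deposited intensities to a common trimmed mean would give, although the sources used here do not state it. By a fixed rule, the values were used as deposited because these means lay within 5% of each other. Such scaling would assume that the bulk of transcripts has the same total in every pool. It would not equalise the medians, which were 234.2, 254.1 and 243.3 and spanned 0.12 on the log2 scale. No detection call accompanies the deposited intensities.

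Gene names came from GEO's platform annotation, which is old, with symbols updated through the Entrez gene number from a RefSeq gene table for 10839 probe sets. A single gene symbol was available for 10855 probe sets, 396 had several symbols and were left out of the gene lists, and 1237 had no symbol here. The 66 control probe sets were used only to describe RNA quality and spiked-in transcripts, which left 12422 probe sets and 8251 named genes. A gene with several probe sets was represented by the one with the highest mean. No genome build is named in the sources used here, so no coordinates are given. Some genes of interest, among them Rp1, had no named probe set in the tables used and were not analysed here.

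Values below 1 were set to 1 before log2. A background limit was set on each array as the 90th percentile of the signal of 97 probe sets of 75 genes restricted to other tissues (liver, pancreas, muscle, germ cells, pituitary and others). By construction some of these probe sets lie above it. A gene below it is described as not above background, not as silent. Signals of different probe sets are not comparable as transcript amounts, so no gene's level was ranked against another's.

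Agreement between arrays was measured as Pearson's r and Spearman's rho of log2 signal across probe sets, which are not independent replicates. The spread was the SD and range of log2 signal over the 3 arrays. The other 26 ordered gene lists for retinal cell types, cells that a dissection could carry along, and general processes were used. These lists, the rules for scaling and for named genes, and the alternatives were fixed before the data were examined. For the 25 lists with 5 or more measured genes, the background list included, the shift on an array was the median over members of log2 signal minus the gene's mean over the 3 arrays. The shift and the median SD were placed among those of 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list was called on an array when it lay outside the central 95% of the random lists. With 75 pairs of list and array, 3.75 calls are expected by chance. These percentiles describe the 3 arrays and are not tests between conditions. The 3 shifts of a list are not independent, since each is taken from the same mean, and genes of a cell type are correlated.

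The shift procedure was tested on simulated data made for 8251 genes from the real means and SDs. It called 10 of 10 lists of 20 genes raised by 1 log2 unit on 1 array, 10 of 10 raised by 0.5 and 7 of 10 raised by 0.25, and it called 3 of 120 pairs with no shift. The simulated noise was independent between genes, and the SDs were shuffled among genes of like mean. Genes of a real list are correlated, so the rate of calls with no shift does not carry over to the real lists.

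The genes named in the text follow a rule: Rp1, the first 4 measured members of each list in its written order, the 10 genes with the largest range of log2 signal, values below background included, among those above the mean background limit on average, and list members above the limit on all arrays with a range over 1 log2 unit. Genes named outside this rule are stated as such, and many of the first kind are given only within counts. Alternatives covered quantile normalisation, median centring, a lowest signal of 20, probe sets with a plain _at suffix only, 2 other background limits (the array median and the 95th percentile of the background list), a filter on dim genes, averaging over a gene's probe sets, and leaving out each pool in turn. The number of arrays limits the precision. SDs come from 3 pools and measure the spread between these samples, which mixes biological and technical variation and averages over the mice in a pool. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.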

Results

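Transcript levels were profiled in the neural retina of wild-type mice at postnatal day 10, an age at which retinal cell division has largely ended and photoreceptors are building their outer segments. The 3 samples, pools of 3 to 4 mice each, form 1 group, the wild-type reference for mice lacking Rp1, a photoreceptor gene. The design therefore asks which transcripts were measurable in this retina and how closely the pools reproduced each signal, which sets the error of any later comparison against the mutant. Signals are in the deposited units, given as mean ± SD over the 3 pools.

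On all 3 arrays, 4444 of 12422 probe sets (35.8%) exceeded the background limit, and 6144 (49.5%) did so on none. The limit was a signal of 331.3 on array 1, 344.1 on array 2 and 285.9 on array 3. Single arrays had 5150, 5170 and 5674 probe sets above it. Median signals of the probe sets for genes restricted to other tissues were 78.2, 95.7 and 69.7. Of 75 such genes, 6 exceeded the limit on all arrays and 58 on none, and Ctrb1, a pancreatic protease gene, read 638.4, 894.3 and 401.3 in pools 1, 2 and 3.

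Transcripts of mature photoreceptors were well represented. In the rod phototransduction list, 10 of 12 measured genes exceeded background on all 3 arrays, among them Pde6b, a catalytic subunit of the rod phosphodiesterase, at 10312 ± 1336 (SD, n = 3), and Sag, rod arrestin, at 27158 ± 6555 (SD, n = 3). All 10 measured genes of the outer segment and cilium list were above background, including Prom1 at 10608 ± 1097, Rom1 at 5018 ± 1192 and Prph2 at 2098 ± 618 (SD, n = 3). Prph2 and Rom1 encode partner proteins of the disc rim. Of 10 photoreceptor transcription factors, 5 were above background on every array. Crx, a regulator of photoreceptor genes, had a signal of 7439 ± 888 and Nrl, which specifies rods, of 561.4 ± 96.6 (SD, n = 3), whereas Rxrg was not above background on any array. In the cone list 4 of 6 genes were above background on all arrays. Opn1sw, the short-wavelength cone opsin, was among the closest between pools at 1557 ± 92.2, and Gnat2, cone transducin, stood at 1074 ± 217 (SD, n = 3). Opn1mw, the medium-wavelength opsin, exceeded background on 2 arrays, with signals of 211.3, 346.1 and 646.7 in pools 1, 2 and 3.

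Inner retinal neurons and glia were also measured. Above background on all arrays were 11 of 18 amacrine cell genes, 9 of 12 ganglion cell genes, 4 of 7 bipolar cell genes, 3 of 7 horizontal cell genes and 9 of 14 Müller glia genes. Gad1, an enzyme of GABA synthesis, had a signal of 2005 ± 335, Slc6a9, a glycine transporter, of 2165 ± 625, and Sncg of 1215 ± 473 (SD, n = 3). The probe set of Gad2 was not above background in any pool. Among bipolar genes Prkca stood at 414.1 ± 49.7 (SD, n = 3) and Trpm1 exceeded background on 2 arrays. Among Müller glia genes, Rlbp1, a retinoid-binding protein, had a signal of 3376 ± 791 and Apoe of 6621 ± 1513 (SD, n = 3). For Glul, glutamine synthetase, the 2 probe sets differed in order. The representative set read 1040.2, 1492.1 and 785.0 in pools 1 to 3, and the other read 371.1, 449.5 and 1002.8. Of 14 synaptic genes, 13 were above background on all arrays, with Snap25 at 7918 ± 1421 and Syt1 at 2130 ± 328 (SD, n = 3).

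Genes of dividing cells and progenitors were above background in part. Of 26 cell cycle genes, 7 were above background on all arrays and 12 on none. Ccnd1, cyclin D1, stood at 886.8 ± 250.4 and Pcna at 1049 ± 204 (SD, n = 3), whereas Mki67 and Top2a, expressed in cycling cells, were not above background in any pool. Of 16 progenitor genes, 5 were above background on all arrays and 5 on none. Notch1, a receptor that holds progenitors undifferentiated, exceeded background in pools 1 and 2 with 784.5 and 807.7 but not in pool 3, with 248.2, whereas a second Notch1 probe set read 253.5, 251.3 and 370.8 and exceeded it only in pool 3. Fgf15 was not above background in any pool.

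Genes of energy metabolism and of the JNK pathway were largely above background. Of 17 glycolysis genes, 15 were above background on all arrays, with Hk1, a hexokinase, at 4965 ± 548 and Pfkl, a phosphofructokinase subunit, at 3089 ± 199 (SD, n = 3). Of 20 oxidative phosphorylation genes, 13 were above background on all arrays, among them Ndufb7 at 3347 ± 763 (SD, n = 3). Of 14 JNK pathway genes, 9 were above background on all arrays, and the 3 JNK kinases were measured at 1611 ± 176 for Mapk8, 570.1 ± 53.3 for Mapk9 and 631.6 ± 33.8 for Mapk10 (SD, n = 3). The circadian clock list had 9 of 14 genes above background on all arrays. Its median SD of 0.21 on the log2 scale lay at the 2.00th percentile of random lists of like signal. Per3 stood at 423.5 ± 77.4 (SD, n = 3), and Csnk1e, the only clock gene above background on all arrays with a range over 2-fold, read 1549.5, 535.6 and 686.0. Of 21 immediate early and heat shock genes, 10 were above background on all arrays, including Egr1 at 566.3 ± 117.7 (SD, n = 3), and Fos was above it on none. Of 12 housekeeping genes 9 were above background on all arrays, with Hprt at 2187 ± 666 (SD, n = 3).

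Markers of pigment epithelium, immune cells, vessels, matrix and blood were measured too. Of 12 genes of pigment epithelium and melanocytes, only Pmel was above background on all arrays, at 544.4 ± 216.8 (SD, n = 3), and Rgr, Ttr, Tyr and Tyrp1 were on none. Of 21 microglia and leukocyte genes 3 were above background throughout, including Cx3cr1, a microglial receptor, at 475.9 ± 52.7 (SD, n = 3). Of 15 endothelial and mural genes 3 were, including Kdr, the VEGF receptor, at 908.3 ± 212.9 (SD, n = 3). Of 16 matrix and fibroblast genes 10 were, including Col1a2 at 1675 ± 250 and Col6a1 at 940.1 ± 220.2 (SD, n = 3). The other 6, Col3a1 among them, were above background on no array. Col1a2 and Col6a1 each have a second probe set, which was not above background on average. Among 9 red blood cell genes only haemoglobin genes were above background on all arrays. Hba-a1 read 19101 in pool 1, 3410 in pool 2 and 12646 in pool 3, and Hbb-b2 read 2328, 883.1 and 1835. These globin probe sets are open to signal from near-identical globin copies.

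The pools agreed across the array with a Pearson's r of log2 signal of 0.90 between pools 1 and 2, 0.88 between pools 1 and 3 and 0.87 between pools 2 and 3, over all 12422 probe sets. Spearman's rho was 0.92, 0.91 and 0.89. These are correlations across genes, which are not independent replicates. The 5215 probe sets above background on average had a median SD of 0.27 on the log2 scale and a median range of 1.42-fold, whereas the 7207 below it had a median SD of 0.68 and a median range of 2.46-fold. A range over 1 log2 unit (2-fold) was reached by 607 of the 5215 (11.6%), with signals below background on single arrays taken as they stand. With 2 arrays the range is smaller by construction, and this count was 350 without pool 1, 248 without pool 2 and 221 without pool 3.

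**Figure D1:**
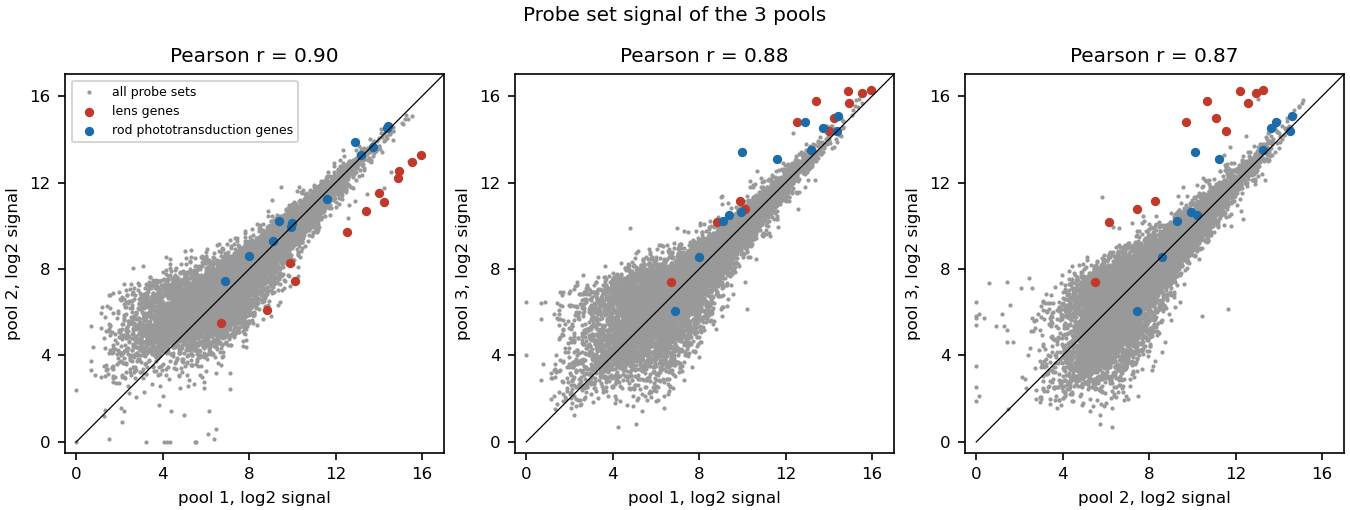
Log2 signal of each probe set (grey) in a pair of pools, with the genes of the lens list (red) and of the rod phototransduction list (blue) marked and the line of equality drawn. Pearson's r is 0.90, 0.88 and 0.87, and the lens genes lie below the line for pools 1 and 2 and above it for pools 2 and 3.

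Lens genes had the widest spread of the 25 lists compared. Every one of the 12 measured lens genes was lowest in pool 2 and highest in pool 3, although 1 of the 12 was above background on no array. Cryaa, the alpha-A crystallin, read 30501 in pool 1, 4703 in pool 2 and 76094 in pool 3, a 16.2-fold range. Crygs read 10984, 1624 and 56437, a 34.8-fold range, and Crybb2 read 5915, 841.9 and 28968, a 34.4-fold range. Genes of the lens fibre other than crystallins followed the same order. Mip, the lens aquaporin, read 457.1 and 1151 in pools 1 and 3 and was not above background in pool 2, so pool 3 was at least 3.34-fold higher than pool 2. Bfsp1, a beaded filament protein, read 1104 and 1726 in pools 1 and 3 and was not above background in pool 2, a range of at least 5.02-fold. Lens probe sets took 3.17%, 0.58% and 5.40% of the summed signal of arrays 1, 2 and 3. The list's median shift was 0.50, -1.96 and 1.35 on the log2 scale, above all 10000 random lists in pools 1 and 3 and below all of them in pool 2. Without pool 2 the shift of pool 1 became -0.37, that of pool 3 became 0.37, and the list's median SD fell from 1.72 to 0.53, and without pool 3 the shifts of pools 1 and 2 became 1.34 and -1.34. Cryba1, Crygb, Crygc, Crygd and Cryge had ranges of 8.63-fold, 7.26-fold, 14.7-fold, 9.01-fold and 8.08-fold, and Cryab, not above background in pool 2, of at least 6.58-fold. Cryge read 79323 in pool 3, the highest signal on array 3, and whether a ceiling narrowed the ranges of the brightest sets was not tested. The probe sets of Crygd, Cryge and Cryab carry the _f_at suffix, which marks a set that can match several family members, and a second Crybb2 set, at 1203, 1333 and 929.8, did not follow the first.

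Rod phototransduction genes differed between the pools as a group. Of the 12 measured, 9 were highest in pool 3 and 9 were lowest in pool 1. Gnat1, the alpha subunit of rod transducin, read 1015 in pool 1, 1101 in pool 2 and 10970.1 in pool 3, a 10.8-fold range. Rcvrn, recoverin, read 3146, 2429 and 8726, a 3.59-fold range. Cnga1, the rod channel subunit, read 665.4, 1189 and 1440.0, and Pde6a read 557.3, 620.3 and 1190 to the nearest unit. Gnb1, a transducin beta subunit also made in other cells, read 7630, 14796 and 28821, and its other 2 probe sets were also lowest in pool 1 and highest in pool 3. Pde6g read 13731, 12851 and 23848. Pdc, phosducin, named here after its values were seen, read 21088, 23619 and 21313. The list's median shift was -0.32 in pool 1, below all 10000 random lists, -0.073 in pool 2, and 0.47 in pool 3, above all of them. Its median SD of 0.53 was at the 99.98th percentile. Without pool 3 the median SD was 0.12, at the 9.86th percentile, and the shift of pool 1 was -0.080, inside the central 95%. Without pool 1 the shift of pool 3 was 0.30, at the 99.8th percentile. The ratio of 3′ to 5′ signal of the Actb controls was likewise lowest in pool 1 and highest in pool 3 (1.20, 1.44 and 1.69), that of Gapdh was not, and lens genes were also highest in pool 3. The outer segment and cilium list shifted by 0.19 in pool 3, at the 94.4th percentile, with Abca4 at 2387, 2037 and 4657 and Reep6 at 3660, 3119 and 6408 in pools 1 to 3. The photoreceptor transcription factors shifted by -0.11 in pool 3, at the 11.4th percentile.

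**Figure D2:**
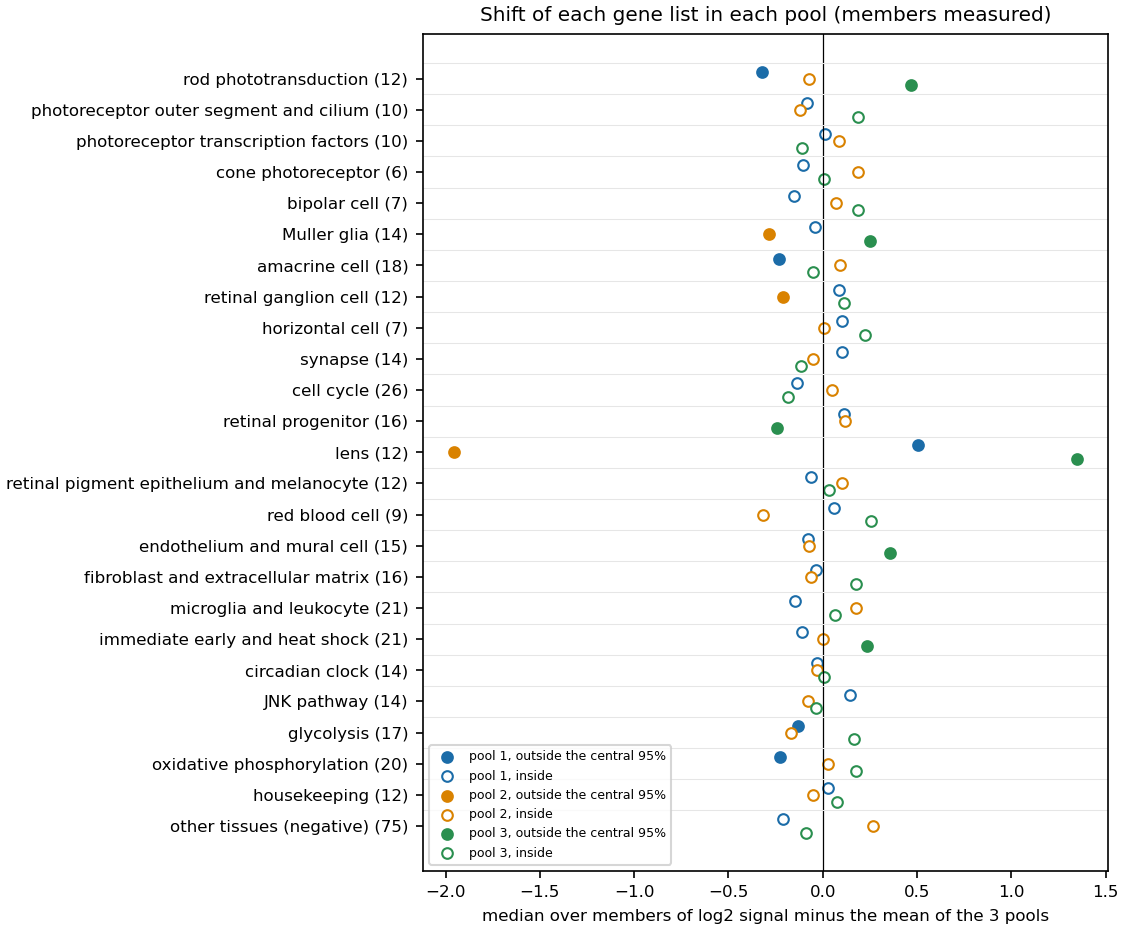
Median over the members of each gene list of log2 signal minus the mean of the 3 pools, for pools 1 to 3, with filled points outside the central 95% of 10000 matched random lists and open points inside it. The lens list spans -1.96 to 1.35, and the rod phototransduction list spans -0.32 to 0.47.

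Across the 75 pairs of list and array, 14 lay outside the central 95% of random lists, against 3.75 expected by chance for lists of unrelated genes. Apart from lens and rod phototransduction they had shifts within 0.36 of 0. Müller glia genes were low in pool 2 (-0.28, 0.38th percentile) and high in pool 3 (0.25, 99.1th percentile), with Clu, clusterin, at 635.8, 702.0 and 2107. Lens genes were likewise lowest in pool 2 and highest in pool 3, as were several bright control probe sets described below. The Actb end ratio was highest in pool 3 (1.69), the pool in which the lists named next were also high. Endothelial and mural genes were high in pool 3 (0.36, 98.3th percentile), with Cldn5, a tight junction protein, at 531.9, 386.4 and 834.4. Of the 15 measured genes of this list, 10 were above background on no array, so most members behind its shift were dim. Too few remained for the endothelial and mural list to be compared with members above background only. Immediate early and heat shock genes were high in pool 3 (0.23, 99.2th percentile), and progenitor genes were low there (-0.24, 1.58th percentile). Ganglion cell genes were low in pool 2 (-0.21, 2.22th percentile), with Nefl, a neurofilament, at 599.3, 437.0 and 1041.5. Amacrine cell genes (-0.23, 0.39th percentile), oxidative phosphorylation genes (-0.23, 0.09th percentile) and glycolysis genes (-0.13, 1.87th percentile) were low in pool 1. The Actb end ratio was also lowest in pool 1 (1.20). Many of these list calls rested on a single pool. Without pool 3, 4 of 50 pairs lay outside, and the shifts of Müller glia genes in pool 2 (-0.10), ganglion cell genes in pool 2 (-0.14) and amacrine, oxidative phosphorylation and glycolysis genes in pool 1 (-0.080, -0.088 and 0.0012) did not. Without pool 2, 10 of 50 lay outside, and those of Müller glia, endothelial, immediate early and progenitor genes in pool 3 (0.14, 0.11, 0.11 and -0.079) and of amacrine genes in pool 1 (-0.13) did not. Without pool 1, 10 of 50 lay outside, and those of immediate early and progenitor genes in pool 3 (0.053 and -0.14) and of ganglion cell genes in pool 2 (-0.13) did not. With members above background only, the amacrine shift turned to 0.10, and the progenitor (-0.091), immediate early (0.10), oxidative phosphorylation (-0.11) and ganglion cell (-0.21) shifts lay inside the central 95%. The endothelial shift (0.31) lay inside it with plain _at probe sets or with averaged probe sets. So did the ganglion cell shift (-0.22 and -0.16), the immediate early shift with plain sets (0.10), and the progenitor and glycolysis shifts with averaged sets (-0.11 and -0.12).

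Other list members above background on all arrays also had a range over 1 log2 unit. Collagen IV genes Col4a1 (1170.0, 862.3 and 2626.0) and Col4a2 (1302, 764.8 and 3557), basement membrane components, and Fbln1 (701.9, 418.9 and 881.8) were highest in pool 3. The same held for Aldoc (1445, 1205 and 3800 to the nearest unit), Pcp2 (1425, 2062 and 3515), Calb2 (3356, 2922 and 6149) and Nsf (1952, 996.0 and 2178). Lowest in pool 3 were Npy, a neuropeptide, at 2427, 1662 and 821.6, Isl1 at 1516, 1681 and 707.4, Gngt2 at 675.0, 1134 and 468.7, and Dab1 at 673.9, 421.4 and 318.8. Prox1 was lowest in pool 2, at 794.4, 396.4 and 719.2.

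Among single genes, Nupr1 and Xist came first by range of log2 signal, an order that rests on signals not above background. As bounds against background their ranges were smaller than those of Crygs and Crybb2. Xist, the transcript that silences an X chromosome and is made in female cells, read 1168 in pool 1 and 3166 in pool 2 and was not above background in pool 3, with 71.5, so pool 2 was at least 11.1-fold higher than pool 3. Of 4 measured Y-linked genes, Kdm5d, Uty and Sry were not above background in any pool. Eif2s3y, on a probe set with the _f_at suffix, read 357.4, 332.2 and 476.5 and was not above background in pool 2. Nupr1, a stress-responsive nuclear protein, read 511.8 in pool 1 and 2575 in pool 3 and was not above background in pool 2, a range of at least 7.48-fold. The probe set that represents Rnh1, the ribonuclease inhibitor, read 635.6 and 973.7 in pools 1 and 3 and was not above background in pool 2, a range of at least 2.83-fold. A second Rnh1 probe set went the other way, at 213.6, 407.3 and 313.0, highest in pool 2 and not above background in pool 1.

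**Figure D3:**
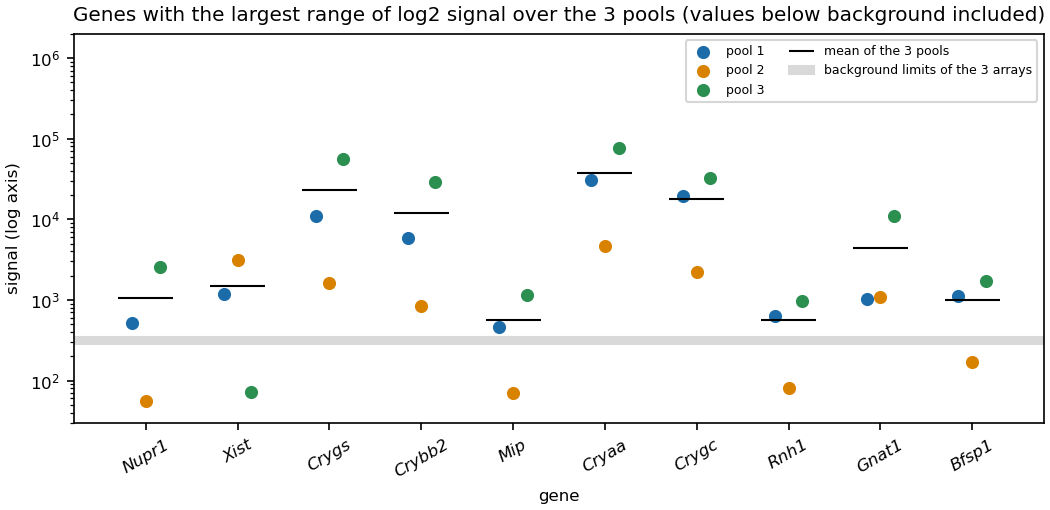
Signal on a log axis of the 10 genes with the largest range of log2 signal, signals below background included, for pools 1, 2 and 3 (points) with their mean (bar) and the background limits of the 3 arrays (grey band, 285.9 to 344.1). Xist is highest in pool 2, and the other 9 genes are highest in pool 3.

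RNA quality was described by control probe sets for the ends of 2 transcripts. The ratio of 3′ to 5′ signal of Gapdh was 0.95, 0.88 and 0.93 in pools 1, 2 and 3, with a mean of 0.92 ± 0.032 (SD, n = 3). That of Actb, beta-actin, was 1.20, 1.44 and 1.69, with a mean of 1.44 ± 0.25 (SD, n = 3). The 3′ control set of Actb read 42626, 21472 and 19848, whereas the probe set that represents Actb among genes read 6156, 6160 and 6048 to the nearest unit. Another Actb probe set read 2594, 3641 and 3734, lowest in pool 1. The Gapdh 3′ control read 33545, 27340 and 41325, lowest in pool 2 and highest in pool 3. Among control sets for spiked-in transcripts, CreX-3 (66004, 43865 and 77330) and BioDn-3 (21317, 17184 and 25257) had this order. So did CreX-5, BioDn-5 and BioC-5. BioB-5, BioB-3 and BioC-3 did not, with BioC-3 at 3519, 3527 and 3514. Whether such technical differences caused list shifts was not tested. No pair of arrays held more than 4 equal values among 12488 probe sets, so no array was a copy of another.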

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

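No alternative was added after the values were seen. The count of probe sets above background on all arrays (4444) ranged from 3203 with the 95th percentile as limit to 5226 with the array median as limit, and the list members above background (182 of 340) from 146 to 214. The count with a range over 2-fold (607) was 357 with the 95th percentile as limit, where only 3868 probe sets were considered, 852 of 6084 with the array median as limit, 635 with median centring, 545 with plain _at probe sets, and 221 to 350 with a pool left out. The mean of the pairwise r (0.885) was 0.901 with a lowest signal of 20 and 0.904 over probe sets above background, both of which by construction level or leave out dim values. The 14 calls of a list on an array became 12 to 16 under the settings that kept all arrays, and 4 to 10 with a pool left out. Of the 14, all were called again with a lowest signal of 20, 13 under quantile normalisation and 11 with plain _at probe sets. Averaged probe sets kept 10, and members above background only kept 8 of 13. All 14 were also called under median centring and either other background limit, but these settings could not change a call. The background limit does not enter the percentiles, and centring moves a list and its random lists alike. The lens calls and both rod phototransduction calls were among those called again in each of these settings. Reversals were the amacrine shift of pool 1 (0.10 with members above background only), the lens shift of pool 1 (-0.37 without pool 2, 1.34 without pool 3) and the glycolysis shift of pool 1 (-0.16 without pool 2, 0.0012 without pool 3). A shift without a pool is taken from another mean. In pool 1 every measured lens gene lay between pools 2 and 3, which fixes the sign of its lens shift when either is left out. The cause of the amacrine and glycolysis reversals was not tested. The 2 lists with a wider spread than random lists became 2 to 4 with a pool left out. Named genes' mean log2 signals moved by more than their SD in 31 recomputed values and by less in 594. Most of the 31 came from averaging over probe sets. Leaving out 1 of 3 pools cannot move a mean by its SD unless another probe set comes to represent the gene. Averaging cannot move a gene with 1 probe set. The 594 is therefore largely fixed by arithmetic and does not measure robustness. Signals near background limit the dim genes, whose median SD was 0.68.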

Other observations

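The tests of explanations for lens genes, rod genes and Xist were chosen after these values had been seen, whereas quantile normalisation had been chosen earlier. Beyond the fixed lists, genes with large ranges went in several directions. Of the 607 probe sets with a range over 2-fold, 194 were highest in pool 1, 191 in pool 2 and 222 in pool 3, and 143, 254 and 210 were lowest there. Genes picked after their values were seen include Drd4, a dopamine receptor made in photoreceptors, at 536.9, 648.0 and 2700 to the nearest unit in pools 1, 2 and 3, and Ptpru at 357.2, 214.4 and 1203, not above background in pool 2. Padi2 was highest in pool 1, at 1118, 581.3 and 167.7, and not above background in pool 3. Skp1, a subunit of a ubiquitin ligase, was highest in pool 2, at 716.4, 3567 and 1497.

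Lens genes differed up to 34.8-fold between pools of the same group. Scaling of the arrays is argued against, since the array medians spanned only 0.12 log2 units, against a median lens shift of -1.96 in pool 2. Quantile normalisation, which can change little when arrays are so alike, left this shift at -1.81. A genotype difference of pool 1 from pools 2 and 3, the split of the titles, is argued against as the whole cause, because pools 2 and 3 lay on opposite sides of pool 1 and differed by a median of 3.52 log2 units over the 8 lens genes above background on all arrays. Lens tissue carried along in different amounts, which a dissection of the neural retina should remove, may explain the pattern but stays open, since Bfsp1 and Mip, the 2 lens genes other than crystallins above background in pools 1 and 3 (median log2 difference 0.99), were already known to go the same way, and crystallins are also transcribed in the retina itself. Whether such material had the same composition in each pool stays open too. The differences between pools 3 and 1 of the 6 lens genes under 50% of the highest signal spanned 1.88 log2 units. Without Crybb2, whose second probe set did not follow the first, they spanned 0.92. Crygs was left out by this cut, and its difference was 2.36, against 0.41 for Crygb. A wide span between pools 3 and 1 therefore did not rest on Crybb2 alone, but each pool gave only 1 array. Between pools 1 and 2 the 8 lens genes above background on all arrays, bright sets included, differed more evenly. Their log2 differences ran from 2.37 (Cryba1) to 3.13 (Crygc), with Crybb2 at 2.81 and Crygs at 2.76.

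Rod phototransduction genes were highest in pool 3, with a median shift of 0.47. Carry-over that follows the lens is argued against, because the rod genes had a median log2 difference of -0.16 between pools 1 and 2, where the crystallins had a median of 2.69. A larger share of rods stays open. None of the 5 photoreceptor transcription factors above background rose in pool 3, where the highest shift was -0.066 (Mef2d) and that of Nrl was -0.17. Apart from Nrl these factors are not restricted to rods, so their shifts do not measure the share of rods. Later retinal development in pool 3 may explain the pattern as a hypothesis, and it predicts fewer progenitor transcripts. The progenitor list shifted by -0.24 there, but this lay inside the central 95% under quantile normalisation, when averaged over probe sets or when limited to members above background, so this explanation cannot be told apart from others, and the higher Actb end ratio of pool 3 and a genotype difference, both untested, also stay open.

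Xist was highest in pool 2, at 3166, and not above background in pool 3. Scaling of the arrays is argued against, since the array medians spanned only 0.12 log2 units. Quantile normalisation, which can change little when arrays are so alike, left a log2 range of at least 3.50, with pool 3 set to its background limit. Different numbers of female mice in the pools may explain it, but only 1 of the 4 measured Y-linked genes, Eif2s3y, was above background on any array (pools 1 and 3), so the Y-linked genes could not decide.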
